A study of Rattus norvegicus with 14 samples.

How the data were processed

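RNA was measured in motor cortex of male rats with a spinal cord injury, on 14 Affymetrix whole-transcript arrays. Per the labels' protocols, rats received MSC or vehicle through the femoral vein 24 hours after injury and were given cyclosporine A, an immunosuppressant, every day. Motor cortex was taken 3 days after the infusion, RNA was purified on columns, and 100 ng of total RNA per array was turned into biotin-labelled target, per the labels' protocols. MSC is the submitters' abbreviation, usually read as mesenchymal stem or stromal cells. The source of the cells is not given in the sources used here.

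The authors deposited log2 expression values made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions and settings of both, and the genome build behind the array annotation, are not given in the sources used here. RMA subtracts a background, equalises the distributions of probe signals across arrays and summarises the probes of each probe set into 1 log2 value. These steps pull small changes towards 0 for dim probe sets, and they can hide a shift that most transcripts share. The values ran from 2.74 to 19.9. Values above about 16 are more than a scanner's usual range gives, so the scale at the bright end is open. Groups are compared only on the same probe set, and the array median serves only as a rough mark of dim signal, since probe sets differ in their response.

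The table held 70580 probe sets. Control probe sets were left out: 31 whose IDs start with AFFX, 155 with ERCC and 1552 with RG, 1738 in all. The RG set, of which 1153 carry a mark for negative controls, was recognised after the IDs were seen, and an alternative keeps it. Of the 68842 tested probe sets, 23446 had exactly 1 gene symbol in the platform's annotation, covering 22093 genes, 505 had several symbols and were not named, and 44891 are unnamed here. Gene symbols were updated through Entrez identifiers and a RefSeq gene table of the rat assembly GRCr8, which changed 1 symbol. A gene with several probe sets is represented by the probe set with the highest mean over all arrays.

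Arrays were grouped by title, source name and treatment, 7 as MSC and 7 as vehicle. The free-text description of MSC replicate 7 names vehicle, against its other labels. It was kept as MSC, and alternatives leave it out or count it as vehicle. Nothing in the labels says that each array came from a separate rat, so p-values measure the spread between these samples, which may in part be technical. No pair of arrays held identical values. For arrays, their number limits the precision: the median half-width of the 95% interval of a log2 difference was 0.15 over probe sets with 1 symbol.

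Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p below 0.05. All differences are MSC minus vehicle on the log2 scale. The separation of the groups over all probe sets was the squared distance between the group means divided by the pooled variance within groups, tested one-sided by exact permutation over all splits into 7 and 7. For 39 gene lists, camera was run with a preset correlation of 0.01 between genes, on 1 probe set per gene, with adjustment over the lists. Camera with an estimated correlation, fry and a two-sided exact permutation of each list's mean per array stood beside it. Single members were also adjusted over their list alone, which does not correct for the 39 lists. Of 1110 list entries, 1041 (93.8%) matched a measured gene, older symbols included. The older symbol Trf, a synonym of both Tf and Trh, was left unmatched after the matches were seen.

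The comparison, its tests, the lists, the alternatives and the rule for named genes were set before the data were examined. Named are the 10 genes per direction with the largest fold among those past the threshold, with empty places filled by the smallest unadjusted p. Also named are the 4 members with the smallest p in the direction of each list past the threshold. Further named are the 2 members with the smallest p of any other list described, and Gfap, Aif1, Bdnf, Gap43 and Fos in any case. For genes named by their p, counts of MSC arrays above or below the vehicle mean restate that choice. Which other lists are described with members was chosen, and widened once, after their values were seen.

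The fit was tested on simulated data with the real number of probe sets and 7 arrays per group. It recovered 73.5% of 200 probe sets changed by 0.5 on the log2 scale and 96% of 200 changed by 1, with 19 false calls among all 68842. Both sets were changed in the same simulated data, and the adjustment is easier to pass when many probe sets change. These shares therefore do not show how often a few isolated changes would be found. In simulated genes with a shift of -0.3 in the immediate early gene list, camera called that list and 0 others. Noise in both simulations was drawn independently for each probe set or gene. The real immediate early genes had an estimated correlation of 0.40, so these recoveries and calls do not show how the tests behave on correlated genes. Alternatives covered array weights, the variance prior, a replicate block, repeated quantile normalization, median centring, a filter on dim probe sets, restriction to probe sets with 1 symbol, the label of MSC replicate 7, the myelin list as a covariate and each array left out in turn. Alternatives added after the data were seen use spike-in control components, a batch seen in the spike-ins, the RG set, exact permutation of list means and the omission of 3 arrays with markers of neighbouring tissue.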

Results

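The data describe the motor cortex, far from the injury, of rats with a spinal cord injury 3 days after an intravenous infusion of MSC or vehicle. There were 7 arrays per group, all from injured animals, so the comparison concerns the infused cells and not the injury. Array medians lay between 5.8 and 5.9 on the log2 scale, and any 2 arrays correlated at 0.990 to 0.997 across probe sets. Spike-in controls set replicates 6 and 7 of both groups apart, with dap at 7.45 to 8.12 against 8.35 to 9.92 on the other arrays. Likewise phe stood at 5.51 to 6.25 against 6.35 to 7.95. No label names a batch, and these gaps are small beside the spread of the other arrays. The batch inferred from them is balanced between the groups, and values within it are given beside each gene list past the threshold.

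The question was which genes of the motor cortex differ between rats infused with MSC and rats infused with vehicle. At the level of single genes the profiles overlapped, and 0 of 68842 probe sets passed an adjusted p of 0.05 in limma. Small shifts shared by gene groups passed only with a preset correlation between genes. That test called 6 of 39 lists, an estimated correlation called 0 (smallest adjusted p = 0.854), fry and exact permutation of list means called 0, and 87 of 100 splits of the arrays gave at least 6 with the preset correlation. Immediate early genes such as Fos and Dusp1 had lower means in the MSC group, with a median log2 difference of -0.28 over 27 genes. Genes of the cytosolic ribosome and of the mitochondrial respiratory chain were also lower, by medians of -0.092 and -0.074. Glutamate receptor, axon guidance and striatal genes had higher medians of 0.057, 0.052 and 0.066. These 3 rested on single arrays, with a glutamate median of 0.033 without vehicle replicate 4, a guidance median of 0.023 without MSC replicate 5 and a striatal median of 0.020 without MSC replicate 6, and each list missed the threshold without that array.

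No single probe set passed, with a smallest adjusted p of 0.9999 in limma, and 2345 had an unadjusted p below 0.05 where chance gives 3442.1. Of these 2345, 689 were higher and 1656 (70.6%) lower in the MSC group. That lean depended on scaling, since 49.6% were lower after repeated quantile normalization (1309 higher, 1290 lower) and 52.9% after median centring (1107 higher, 1242 lower). The groups were separated by 0.24 over all probe sets, and 1225 splits gave as much out of all splits into 7 and 7 (exact permutation p = 0.714, one-sided). The 95% interval excluded a 1.5-fold difference in either direction for 97.7% of probe sets with 1 symbol, and a 2-fold difference for 99.7%. These shares include dim probe sets, whose differences RMA pulls towards 0. For those, a narrow interval does not exclude such a change in the transcript.

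Among the genes with the smallest unadjusted p, none of which passed the adjustment, those higher in the MSC group included enzymes and nuclear proteins. Pde10a, a cyclic nucleotide phosphodiesterase, was at 10.77 ± 0.25 against 10.18 ± 0.24 (SD, 7 arrays each), a difference of 0.58 ± 0.12 (SE), and all 7 MSC arrays lay above the vehicle mean. Pde10a has 2 probe sets, of which only the brighter is given. Car11, a carbonic anhydrase-related protein, differed by 0.61 ± 0.15. Smaller differences were measured for Dctd (0.43), Slc35f3 (0.35), Irf3, a transcription factor of the interferon response (0.31), and Pabpn1, a nuclear poly(A)-binding protein (0.30). Fam227a (0.28), Nol4l (0.22), Hmgn2l2 (0.21) and Cdk10 (0.21) completed the 10. Each had an adjusted p of 0.9999 in limma.

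Lower in the MSC group were Dusp1, a phosphatase of MAP kinases (-1.36 ± 0.35, SE), Ifit3, an interferon-induced gene (-0.43 ± 0.12), and Rpl37l2 (-0.38 ± 0.076). Msgn1 differed by -0.38, with group means of 4.32 and 4.70. Klf4-ps1 (-0.31), Snrpgl2 (-0.29), LOC103690878 (-0.28), LOC102547452 (-0.23) and LOC102552075 (-0.23) are little-described genes or copies. Rpl37l2, Snrpgl2 and Klf4-ps1, and Hmgn2l2 among the higher genes, carry the names of other genes' copies. Signal from the parent genes cannot be separated here. Ppp1r15a, the subunit that directs dephosphorylation of eIF2alpha in the stress response, differed by -0.27 ± 0.069. Both group means of Msgn1, Ifit3, Ppp1r15a, Klf4-ps1, LOC103690878, LOC102547452 and LOC102552075 lay below the lowest array median of 5.77, a rough mark of dim signal. These also had adjusted p of 0.9999 in limma, and no named gene outside the fixed markers turned its sign when any array was left out. Genes outside the fixed markers were chosen for a small p in these same arrays, so the kept signs are no independent support.

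Of the 39 gene lists, 6 passed the threshold in camera with the preset correlation, 3 lower and 3 higher in the MSC group. None of the 6 held with an estimated correlation, where the smallest adjusted p was 0.854, and 0 lists passed in fry or by exact permutation of list means. At an unadjusted p below 0.05, the estimated correlation, fry and exact permutation each left 1 list.

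Immediate early genes are switched on within minutes by neuronal activity. Of 27 measured members, 22 had lower means in the MSC group, and the list passed in camera (adjusted p = 4.27e-07). With an estimated correlation the adjusted p = 0.860. Fos was at 8.17 ± 0.92 in MSC and 9.24 ± 0.48 in vehicle arrays (SD, 7 each), 2.10-fold higher in vehicle. Dusp1 was at 10.54 ± 1.02 and 11.90 ± 0.28, 2.56-fold higher in vehicle. Ier2 (-0.91 ± 0.25, SE) and Sik1, a kinase of CREB coactivators (-0.52 ± 0.19), lay the same way, each with 6 of 7 MSC arrays below the vehicle mean. Adjusted over the list alone, Dusp1 and Ier2 passed, and 0 members passed over all genes tested. The list's mean differed by -0.33 ± 0.16 (SE, exact permutation p = 0.066, two-sided; adjusted over the lists, p = 0.859). Within replicates 1 to 5 the mean difference was -0.45 ± 0.19 (SE). Within replicates 6 and 7, with 2 arrays per group, it was -0.038 ± 0.18, too imprecise to show that the pattern was absent there.

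**Figure D1:**
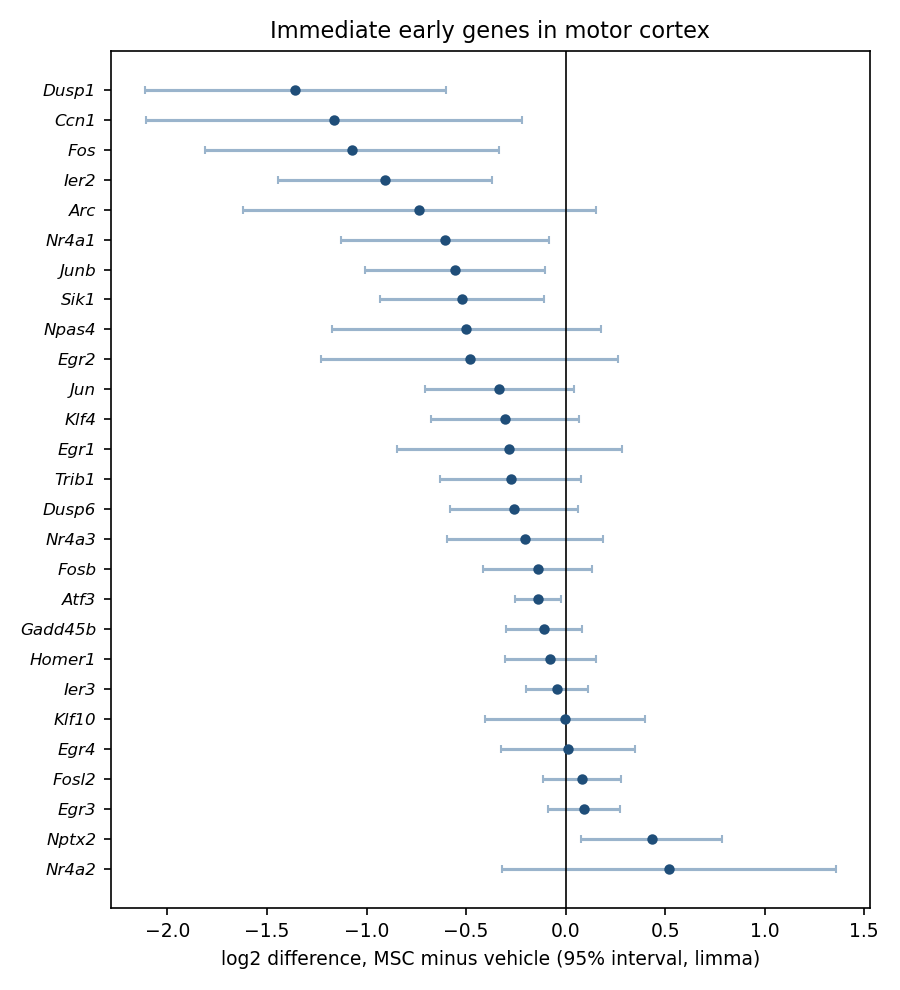
Log2 difference, MSC minus vehicle, of the 27 measured immediate early genes, with the 95% interval from limma over 7 arrays per group. Of these, 22 lie below 0, with Dusp1 at -1.36 and Fos at -1.07, and none passed the adjustment over all genes.

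Cytosolic ribosomal protein genes had lower means for 63 of 69 members (camera adjusted p = 3.26e-11; adjusted p = 0.854 with an estimated correlation). Rpl38 differed by -0.34 ± 0.12 (SE), Rpl8 by -0.30 ± 0.089, Rps24 by -0.29 ± 0.085 and Rps12 by -0.17 ± 0.053. Rpl8 has 3 probe sets and Rpl38 and Rps24 have 2 each, of which only the brightest is given. Those given for Rpl38 and Rpl8 have IDs marked as unmapped. The list's mean was 10.68 ± 0.094 in MSC and 10.78 ± 0.054 in vehicle arrays (SD; exact permutation p = 0.024, two-sided; adjusted over the lists, p = 0.859). In the nuclear-encoded respiratory chain, 58 of 67 members had lower means (adjusted p = 1.73e-06; adjusted p = 0.860 with an estimated correlation). Ndufb10 (-0.23), Ndufb8 (-0.16), both of complex I, Uqcrh of complex III (-0.16) and Atp5pd of the ATP synthase (-0.20) are examples. Adjusted over the list alone, 0 members of either list passed, and 0 over all genes tested. Within replicates 1 to 5 the mean differences were -0.13 ± 0.044 (SE, ribosome) and -0.093 ± 0.049 (respiratory chain). Within replicates 6 and 7, with 2 arrays per group, they were -0.036 ± 0.040 and -0.024 ± 0.042.

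Glutamate receptor and postsynaptic density genes had higher means for 29 of 40 members (camera adjusted p = 0.0018; adjusted p = 0.860 with an estimated correlation). Gria1, an AMPA receptor subunit, differed by 0.45 ± 0.21 (SE), Baiap2 by 0.28 ± 0.13, Cnih2, an AMPA receptor auxiliary protein, by 0.26 ± 0.14 and Grm5 by 0.15 ± 0.083. Of the axon guidance and growth inhibition genes, 32 of 44 had higher means (adjusted p = 0.013; adjusted p = 0.860 with an estimated correlation). Dcc, a netrin receptor, differed by 0.42 ± 0.18, Slit1 by 0.39 ± 0.17, Epha7 by 0.34 ± 0.17 and Nrp1, a semaphorin receptor, by 0.32 ± 0.15. Dcc has 2 probe sets, of which only the brighter is given. Adjusted over the list alone, 0 members of either list passed, and 0 over all genes tested. Within replicates 1 to 5 the mean differences were 0.11 ± 0.074 (SE, glutamate) and 0.084 ± 0.073 (guidance). Within replicates 6 and 7, with 2 arrays per group, they were -0.0037 ± 0.090 and 0.023 ± 0.056. Both medians rested on single arrays: without MSC replicate 5 the guidance median was 0.023, without MSC replicate 3 it was 0.081, without vehicle replicate 4 the glutamate median was 0.033 and without MSC replicate 3 it was 0.091. Without MSC replicate 5 neither list passed (adjusted p = 0.297 for guidance and 0.129 for glutamate), nor without vehicle replicate 4 (0.096 and 0.080), and guidance did not pass without vehicle replicate 6 (0.056). The guidance list no longer passed with dim probe sets left out (adjusted p = 0.075), after quantile normalization (adjusted p = 0.082) or median centring (adjusted p = 0.072), and with MSC replicate 7 counted as vehicle neither list passed (adjusted p = 0.077 for guidance and 0.065 for glutamate).

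**Figure D2:**
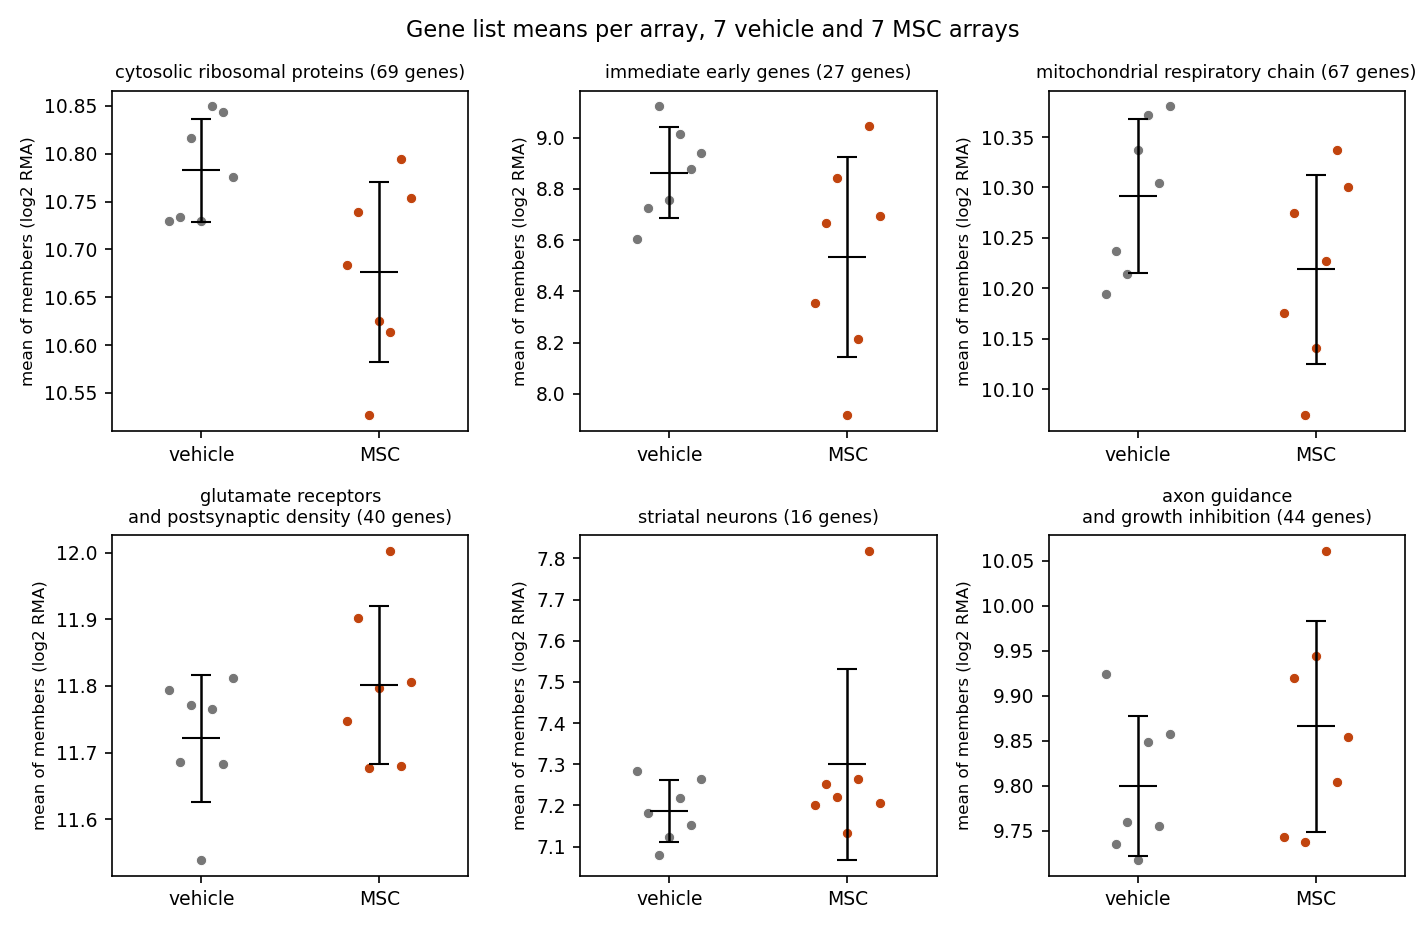
Mean of the measured members per array, as log2 RMA values, for the 6 gene lists past the camera threshold, with 7 vehicle and 7 MSC arrays as points and the mean and SD in black; vertical axes differ and do not start at 0. Both groups overlap in every panel, and MSC replicate 6 stands apart for striatal neurons at 7.82.

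Striatal neuron markers had higher means in the MSC group for 12 of 16 members (camera adjusted p = 0.0022; adjusted p = 0.860 with an estimated correlation). Besides Pde10a, the dopamine receptor Drd2 differed by 0.32 ± 0.18 (SE), the adenosine receptor Adora2a by 0.20 ± 0.13 and Syndig1l by 0.089 ± 0.053. Adjusted over the list alone, Pde10a passed, and 0 members passed over all genes tested. The list stood at 7.82 in MSC replicate 6 and at most at 7.26 in the other MSC arrays. Without that array the median was 0.020 and the list did not pass (adjusted p = 0.233), and Drd2 differed by 0.14, Adora2a by 0.079 and Syndig1l by 0.057. Within replicates 1 to 5 the mean difference was 0.037 ± 0.043 (SE). Within replicates 6 and 7, with 2 arrays per group, it was 0.30 ± 0.31.

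**Figure D3:**
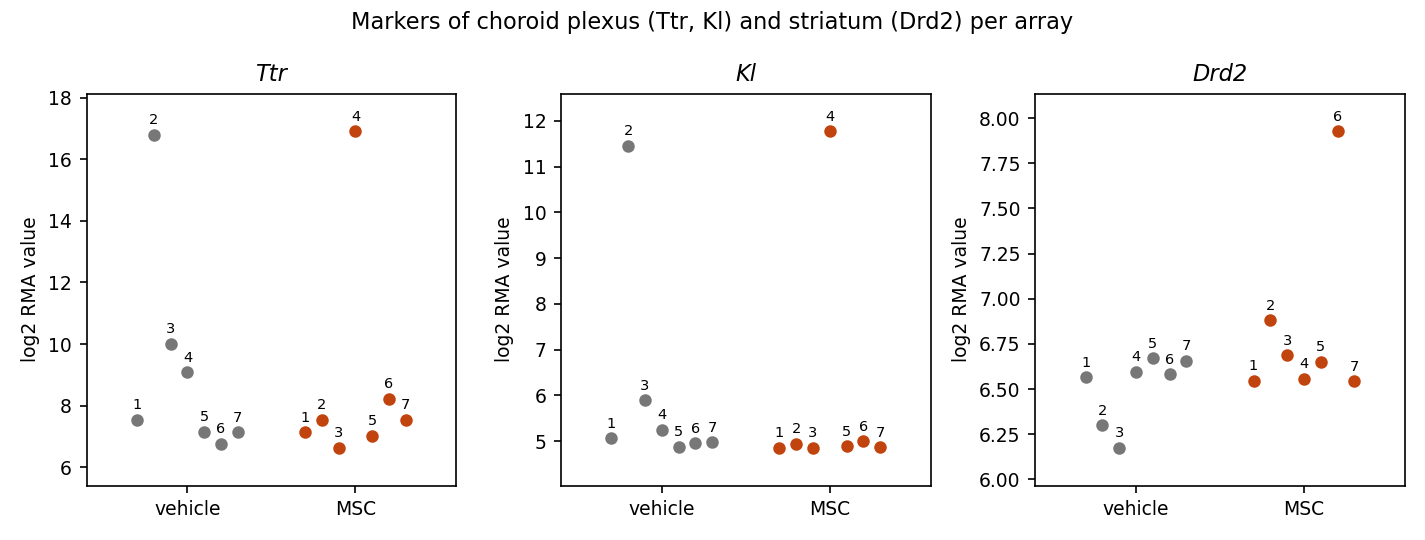
Log2 RMA values of Ttr and Kl, markers of the choroid plexus, and Drd2, a striatal marker, on each array, with replicate numbers beside the points; axes do not start at 0. Ttr stood at 16.9 in MSC replicate 4 and 16.8 in vehicle replicate 2, and Drd2 at 7.93 in MSC replicate 6.

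Markers of glia and inflammation showed no list past the threshold. The microglia list had 10 of 19 members lower and a median of -0.0013 (camera adjusted p = 0.879), with the homeostatic receptor P2ry12 at -0.27 ± 0.094 (SE) and the integrin Itgam at 0.17 ± 0.084. Its median and mean lay below 0 while the camera direction was up. Aif1, the usual microglial marker, was at 6.10 ± 0.060 in MSC and 6.08 ± 0.076 in vehicle arrays (SD), and Gfap, the astrocyte filament, at 10.83 ± 0.59 and 10.72 ± 0.73. Reactive astrocyte genes had a median of 0.016 over 26 members (adjusted p = 0.339), with Emp1 at 0.14 and Serpina3n at 0.092. Cytokines, chemokines and adhesion molecules had a median of -0.013 over 36 members (adjusted p = 0.744), with Ccl7 at -0.17 and Sele, an endothelial selectin, at -0.082. Interferon-stimulated genes had a median of -0.014 over 36 (adjusted p = 0.240), with Ifit3 at -0.43 and Gbp5 at -0.13. Myelin genes had a median of -0.033 over 20 (adjusted p = 0.684), with Qdpr at -0.23 and Hapln2 at 0.38. Single arrays moved these medians over a wide range. Without MSC replicate 4 the myelin and interferon lists passed as lower, at -0.10 (adjusted p = 0.013) and -0.034 (adjusted p = 0.00998), and without MSC replicate 4, MSC replicate 6 and vehicle replicate 2 together they stood at -0.18 (1.47e-04) and -0.044 (0.014). The other way, the myelin median was 0.040 without vehicle replicate 5 and the interferon median 0.021 without MSC replicate 2. With 1 array left out the microglia median ran from -0.021 (MSC replicate 2) to 0.035 (MSC replicate 4) and that of reactive astrocytes from 0.00070 (MSC replicate 3) to 0.032 (MSC replicate 5). That of cytokines ran from -0.030 (vehicle replicate 3) to 0.00011 (MSC replicate 2). Both group means of Ifit3, Ccl7, Sele and Serpina3n lay below the median of every array. Serpina3n differed by 0.048 without MSC replicate 5, and Gfap by 0.11 with all arrays and by -0.038 without vehicle replicate 4. Serpina3n has 2 probe sets, of which only the brighter is given.

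Endothelial genes came closest to the threshold among the lists that missed it, with 14 of 22 members lower and a median of -0.060 (camera adjusted p = 0.058; adjusted p = 0.890 with an estimated correlation). The call turned with scaling: the list passed after repeated quantile normalization (adjusted p = 0.020) and after median centring (0.033). It also passed with dim probe sets left out (0.036), with MSC replicate 7 counted as vehicle (0.017) and in 6 of the fits that leave out 1 array. Without MSC replicate 4 the median was -0.0085. Cldn5, a tight junction protein of the blood-brain barrier, differed by -0.30 ± 0.093 (SE) and Ly6c by -0.33 ± 0.092, each lower in 7 of 7 MSC arrays than the vehicle mean. Both group means of Ly6c lay below the median of every array. Ly6c has 4 probe sets, of which only the brightest is given, and its ID is marked as unmapped. Adjusted over the list alone, 0 members passed. Markers of mesenchymal stromal cells had a median of 0.0064 over 14 members (adjusted p = 0.879), and of -0.040 without MSC replicate 2 to 0.026 without MSC replicate 1. Among these, Itgb1 was at -0.10 and Thy1, also a neuronal gene, at 0.14. Thy1 differed by 0.082 without vehicle replicate 3, and Itgb1 by -0.069 without vehicle replicate 2.

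Genes of growth and regeneration also missed the threshold. Neurotrophic and growth factors had a median of 0.034 over 36 members (camera adjusted p = 0.228), with the neurotrophin receptors Ntrk3 at 0.23 ± 0.10 (SE) and Ntrk2 at 0.12 ± 0.073. That list passed without vehicle replicate 2 (median 0.050, adjusted p = 0.033), and without MSC replicate 4, MSC replicate 6 and vehicle replicate 2 together (0.050, 0.0028), and had a median of 0.019 without MSC replicate 2. Bdnf was at 5.89 ± 0.12 in MSC and 5.84 ± 0.085 in vehicle arrays (SD). Axon growth and regeneration genes had a median of 0.032 over 37 (adjusted p = 0.404), with the injury-response factor Atf3 at -0.14 and Smad1 at -0.093. Group means of Atf3, 5.77 in MSC and 5.91 in vehicle arrays, also lay near the array medians. The axon growth median was 0.0025 without vehicle replicate 3 and 0.057 without vehicle replicate 7. Gap43, a growth cone protein, was at 11.56 ± 0.26 and 11.54 ± 0.30. Ntrk2 differed by 0.076 without MSC replicate 5. Single arrays also moved the small differences of Bdnf, Aif1 and Gap43. Bdnf differed by 0.049 with all arrays and by 0.013 without MSC replicate 3. Aif1 differed by 0.021 with all arrays and by 0.0013 without vehicle replicate 1, and Gap43 by 0.019 with all arrays and by -0.044 without MSC replicate 7. Markers of deep layer and corticospinal neurons, whose axons run to the cord, had a median of 0.043 over 22 members (adjusted p = 0.301), with Rprm at -0.14 and Foxp2 at -0.12 (-0.075 without MSC replicate 4). Their median was 0.025 without MSC replicate 2 and 0.10 without vehicle replicate 7.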

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

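The tests on immediate early, ribosomal, respiratory and striatal genes, and the within-batch values, were chosen only after these patterns were seen, and for arousal, the time of day, the striatal piece and the splits at adjusted p values that enter the test had been seen too. At adjusted p below 0.05 the real split gave 0 probe sets and the highest other of 100 drawn splits 18; with 0 all 100 give as many whatever the data hold, so this count tells nothing about chance. Chance assignment of arrays to groups cannot be excluded for the other 2 counts. At unadjusted p below 0.05 the real split gave 2345, the highest other 9612, and 75 of 100 gave as many. For gene lists the real split gave 6, the highest other 24, and 87 of 100 gave as many. The split with 9612, several times the real count, points to a structure of the samples apart from the groups. Its sides differ by 39.0 on the leading principal component where the real split differs by 11.0. A split with 7132 differs by only 2.7, so that component does not account for every high count. The split with 9612 does not follow the spike-in batch, with 2 of the batch's 4 arrays on its side with MSC replicate 1.

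Immediate early genes had lower means in the MSC group in camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.860) and by exact permutation (adjusted p = 0.859). Brief arousal or handling in the minutes before the tissue was taken is a candidate explanation, as it would spare delayed activity-regulated genes. The mean of 13 of these differed by 0.146 ± 0.080 (SE, exact permutation p = 0.093), with 3 members lower. The prediction set no upper limit, so a rise of any size met it, and sparing alone would give no rise. The fall of 16 rapid genes, -0.53 ± 0.22, restates the pattern, as Fos and Dusp1 had been seen, and is no evidence for this explanation. The batch inferred for replicates 6 and 7 holds 2 arrays of each group, so a shift between these sets cancels from the group difference. Other batches were not tested. Whether the groups differed in the time of day at which tissue was taken is undecided. The evening minus morning clock score differed by 0.197 ± 0.12 (SE, exact permutation p = 0.128), after Bmal1 and Nfil3 had been seen. The arrays were too few to set it below the bound of 0.3. Chance (exact permutation p = 0.066 for the list) and an effect of the infused cells on cortical activity also stay open, the latter untested.

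Ribosomal and respiratory chain genes had lower means in the MSC group in camera with the preset correlation, calls lost with an estimated correlation (adjusted p = 0.854 and 0.860) and by exact permutation (adjusted p = 0.859 for both). A general fall of bright genes with a short span is argued against. The ribosomal median of -0.092 lay below the 2.5th percentile, -0.021, of 10000 random lists matched on level and gene span. The respiratory median, -0.075 over the 66 members with a known span, lay below -0.010. The matched random lists themselves centred on 0.013 and 0.017, so matched genes showed no fall. Members of the real lists are correlated, at an estimated 0.17 and 0.21, and lists of unrelated genes vary less. Lying below their range therefore does not exclude chance. Gene span on GRCr8 includes introns and stood in for transcript length, so short transcripts as such were not tested, and the explanation was narrowed from transcripts to span after the result was known. RNA quality, chance and the infused cells may each remain as explanations, and the first has no measurement here.

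Striatal markers had higher means in the MSC group in camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.860) and without MSC replicate 6 (adjusted p = 0.233). Striatal tissue in the piece from 1 animal is a candidate explanation. The list's mean differed by 0.113 with MSC replicate 6 and by 0.027 without it. That array was singled out for its high list mean, so this fall restates the pattern and is no evidence for the explanation. All 16 measured members were higher in that array than the mean of the other 13, with Rgs9 at 8.87, Penk at 8.97 and Drd1 at 8.19 against vehicle means of 7.28, 7.79 and 7.07. Of the 16, 1 is held by another list, and 8 lay above the median gene level of 6.78 in the other 13 arrays. Levels of different probe sets compare only roughly, and how far the members are expressed in cortex was not tested otherwise. Pde10a is not covered by this, at 10.75 in the mean of the other 6 MSC arrays against 10.18 in vehicle, and chance and the infused cells stay open.

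Single arrays far from the rest of their group were counted over 232 groups of 7, of which 21 held 1, where chance gives about 11.6. Choroid plexus and ependyma markers stood at 8.14 in MSC replicate 4 and 8.26 in vehicle replicate 2, with medians of 5.98 among the other arrays of each group. Meningeal and fibroblast markers stood at 8.25 in MSC replicate 2 (others' median 7.31) and at 8.25 in vehicle replicate 2 (7.28). The striatal list stood at 7.82 in MSC replicate 6 (7.21), as did Drd2 at 7.93 (6.6), Ier2 at 7.49 (6.41) and the cell cycle list at 6.03 (5.9). MSC replicate 2 was high for the astrocyte list at 11.3 (11.0), deep layer and corticospinal neurons at 10.1 (9.82), Emp1 at 7.05 (6.71), Rgs16 at 7.20 (6.69) and Vamp2 at 15.4 (15.0). Upper layer neurons stood at 9.84 in MSC replicate 5 (9.33). Low values were Dcc at 8.89 (9.84) and Ly6c at 4.43 (4.97) in MSC replicate 1, Cldn5 at 8.09 in MSC replicate 3 (8.46) and 8.30 in vehicle replicate 4 (8.74), and Ntrk3 at 11.5 in vehicle replicate 2 (12.1). Ppp1r15a stood at 5.94 in vehicle replicate 3 (5.55) and Qdpr at 11.1 in vehicle replicate 4 (10.6).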

How the results depend on the processing

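The alternatives with control components, the spike-in batch, the RG set, exact permutation of list means and the omission of 3 arrays were chosen after seeing the data. In limma, 0 probe sets passed the adjusted threshold under every alternative fit, and 567 passed an unadjusted p below 0.05 together with a 1.2-fold difference. The 2345 at unadjusted p below 0.05 became 979 without dim probe sets and 829 with only probe sets of 1 symbol, since fewer were tested, and 1929 to 3417 when 1 array was left out. The separation of 0.24 stayed between 0.22 and 0.33 with 1 array left out (exact permutation p 0.296 to 0.907). The 6 lists became 0 with an estimated correlation, 0 in fry and 0 by exact permutation of list means. They became 5 to 12 with 1 array left out (5 without MSC replicate 5, 12 without MSC replicate 4, 10 without vehicle replicate 2) and 13 without MSC 4, MSC 6 and vehicle 2; the cause was not tested. In all, 15 lists that missed the threshold passed it under some alternative, endothelial cells under 10 and synaptic vesicle under 9. Choroid plexus passed as lower without MSC replicate 4 and as higher without vehicle replicate 2. Ribosomal, immediate early and respiratory lists passed with every single array left out. Replicate numbers gave no clear pairing of the arrays: same-numbered arrays correlated at -0.31 to 0.27 and 4 of 14 matched their own number best. The correlation was 0.27, 0.10 and 0.14 for replicates 5, 6 and 7, 0.010 for replicate 4 and negative for replicates 1 to 3. Pairing is therefore undecided. With the replicate block, 2278 probe sets had an unadjusted p below 0.05, 8 lists passed and the separation was 0.224. Most named genes were chosen for a small p in these same arrays, and 0 probe sets passed in any fit. A kept sign or side of the threshold therefore says little about them. Of 2066 values of 77 named genes under alternatives, 2054 kept sign and side. The other 12 turned sign, all for fixed markers near 0; the cause was not tested. Gap43 was -0.0033 with array weights, -0.095 with MSC replicate 7 as vehicle and -0.044 to 0.11 with 1 array left out. Aif1 was -0.0040 with MSC replicate 7 as vehicle. Gfap was -0.040 without the 3 arrays and -0.038 to 0.34 with 1 array left out. Dim probe sets near the array background limit what small differences can show.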

Other observations

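Several groups of neuronal genes had medians above 0 without passing the list threshold. Voltage-gated channels had a median of 0.022 over 33 members (camera adjusted p = 0.397) and of -0.016 without MSC replicate 5, yet Scn3b, a sodium channel beta subunit, differed by 0.69 ± 0.24 (SE) and Kcnab1, a potassium channel beta subunit, by 0.39 ± 0.13, each higher in 7 of 7 MSC arrays than the vehicle mean. GABA receptor genes had a median of 0.037 over 19 (adjusted p = 0.148), with Gabra5 at 0.40 and Gabrb1 at 0.33. It passed without vehicle replicate 5 (median 0.056, adjusted p = 0.021) and without the 3 arrays named below (0.10, 0.021), and its median was 0.016 without MSC replicate 2 and 0.071 without MSC replicate 3. Synaptic vesicle genes had a median of 0.052 over 31 (adjusted p = 0.079). This list passed with array weights (adjusted p = 0.011), with the replicate block (0.039), without the 3 arrays named below (0.0064) and in 6 of the fits that leave out 1 array, while its median was 0.015 without vehicle replicate 3. Its members include Vamp2 at 0.14 (0.076 without MSC replicate 2) and Syt2 at -0.33. Thalamic and hippocampal markers had a median of 0.019 over 17 (adjusted p = 0.157), with Wfs1 at 0.74 ± 0.32 and Rgs16 at 0.19 (0.13 without MSC replicate 2). They passed without MSC replicate 6 (median 0.048, adjusted p = 0.032) and without vehicle replicate 3 (0.031, adjusted p = 0.048), and the median was 0.0045 without vehicle replicate 5 and 0.077 without MSC replicate 1. GABAergic interneuron markers had a median of 0.022 over 23 (adjusted p = 0.301), with the calcium buffer Pvalb at -0.26 and Gad2 at 0.19. They passed without MSC replicate 4 (median 0.044, adjusted p = 0.015), and the median was -0.00051 without MSC replicate 5 and 0.064 without vehicle replicate 5. None of these genes passed the adjustment over all genes.

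The core clock factor Bmal1 differed by -0.30 ± 0.084 (SE), with 6 of 7 MSC arrays below the vehicle mean, and Nfil3, with both group means below every array median, by -0.15 ± 0.053. Adjusted over the list alone, Bmal1 passed, and 0 clock genes passed over all genes tested. The clock list had a median of -0.020 over 18 (camera adjusted p = 0.455), from -0.045 without MSC replicate 5 to 0.029 without vehicle replicate 1. It mixes evening and morning clock genes, so opposite shifts of these cancel in the median and in camera. The evening minus morning score differed by 0.197 ± 0.12 (SE, exact permutation p = 0.128). In the unfolded protein response list, Ppp1r15a, with both group means below every array median, differed by -0.27 and passed adjusted over the list alone. Without vehicle replicate 3, an outlying array for this gene, Ppp1r15a differed by -0.21. Atf3 stood at -0.14. The list's median was -0.019 over 25 (camera adjusted p = 0.427), from -0.038 without MSC replicate 6 to 0.0099 without vehicle replicate 7.

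The remaining lists missed the threshold with all arrays, and single arrays moved each of their medians by over 1.5 times. Astrocytes had a median of 0.062 (camera adjusted p = 0.228), of 0.028 without MSC replicate 2, and passed without vehicle replicate 1 (0.087, adjusted p = 0.0060). Oligodendrocyte precursors had a median of -0.045 (0.301), of -0.021 without MSC replicate 3 and -0.070 without vehicle replicate 2, and passed without MSC replicate 4 (-0.054, adjusted p = 0.029) and without the 3 arrays named below (-0.078, 0.024). Pericytes and smooth muscle had -0.024 (0.455), 0.011 without vehicle replicate 2, and passed without MSC replicate 2 (-0.080, adjusted p = 0.041). Meninges and fibroblasts had 0.072 (0.301) and -0.052 without MSC replicate 2. They passed without vehicle replicate 2 (0.20, adjusted p = 6.31e-06), without the 3 arrays (0.32, 2.79e-10) and with the replicate block (adjusted p = 0.040). The list's mean was 8.25 in both MSC replicate 2 and vehicle replicate 2. The fits without vehicle replicate 2 and without the 3 arrays leave out the high array of the vehicle group alone. Erythrocytes had 0.020 (0.301), 0.055 without MSC replicate 2, and passed without vehicle replicate 4 (0.033, adjusted p = 0.017). Cholesterol synthesis had -0.050 (0.228), 0.022 without vehicle replicate 1, and passed without vehicle replicate 2 (-0.080, adjusted p = 0.0033) and without the 3 arrays (-0.087, 0.021). Choroid plexus and ependyma had -0.045 (0.980), where the camera direction was up, and passed in opposite directions without MSC replicate 4 (-0.15, adjusted p = 0.00998) and without vehicle replicate 2 (0.19, adjusted p = 0.0028).

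The lists that follow passed in no fit that leaves out 1 array. Phagocytic myeloid cells had a median of 0.019 (camera adjusted p = 0.881), from -0.0026 without MSC replicate 2 to 0.052 without vehicle replicate 2. Lymphocytes and neutrophils had -0.012 (0.689), from -0.030 without MSC replicate 3 to 0.0060 without MSC replicate 7. Upper layer neurons had -0.025 (0.980), where the camera direction was up, from -0.089 without MSC replicate 5 to 0.0019 without MSC replicate 1. Complement had -0.0013 (0.629), where the mean and the camera direction were up, from -0.021 without MSC replicate 2 to 0.020 without vehicle replicate 1. Antigen presentation had -0.012 (0.689), from -0.027 without MSC replicate 1 to -0.0034 without vehicle replicate 2. The glucocorticoid response had -0.034 (0.770), from -0.061 without vehicle replicate 4 to 0.020 without vehicle replicate 6. Perineuronal net and matrix had 0.019 (0.506), from -0.0028 without MSC replicate 2 to 0.046 without vehicle replicate 2. The cell cycle had -0.019 (0.455), from -0.029 without MSC replicate 6 to -0.0099 without vehicle replicate 2. Heat shock had 0.0076 (0.980), where the mean and the camera direction were down, from -0.012 without vehicle replicate 2 to 0.018 without MSC replicate 4.

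The choroid plexus marker Ttr, a thyroid hormone carrier, stood at 16.9 in MSC replicate 4 and 16.8 in vehicle replicate 2, and at 6.63 to 10.01 in the other arrays. Kl stood at 11.8 and 11.5 in these arrays. Without MSC replicate 4, MSC replicate 6 and vehicle replicate 2, 13 lists passed in camera, and the striatal list did not (median 0.035, adjusted p = 0.070).

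MSC replicate 7, whose description names vehicle, was left out or counted as vehicle without any probe set passing the adjusted threshold. Counted as vehicle, it gave 2801 probe sets at unadjusted p below 0.05 and 5 lists past the threshold.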
